A study of Mus musculus with 8 samples.

How the data were processed

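Total RNA of sorted mouse bone marrow cells was measured on 8 single-colour expression arrays with a biotin label, 4 labelled KLF7 and 4 labelled control. Per the labels' protocols, c-Kit-positive cells were transduced, the lineage-negative, c-Kit-positive, Sca-1-positive cells were sorted 72 hours later, and the RNA was amplified before it was hybridised. Amplification of the RNA and background correction can compress differences between dim genes, which no value here corrects. The values deposited are probe set intensities, which the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalises between arrays and summarises the probes of a probe set. The versions, the level of summary, any later step and a genome build are not given in the sources used here, and no coordinates are therefore printed.

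The deposited intensities ran from 2.20 to 15393 with no missing value, a linear scale, so log2 was taken before every test, as the design written before the data were examined had foreseen. Of 35554 probe sets, 21789 carried 1 gene symbol in the platform's annotation, 1621 several and 12144 none. Of the 21789, 21698 were matched by Entrez number to the RefSeq table of assembly GRCm38, and 0 symbols changed. No gene was named from a probe set with several symbols, and for this reason Ly6a (which encodes Sca-1) and Cdkn1a, which the rule for named genes lists, are not analysed here. For the 999 genes with more than 1 probe set, the one with the highest mean over all arrays was kept before the fit, which left 19938 genes, with no filter on dim ones. The 6615 probe sets numbered below the first annotated one were taken as control probe sets.

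Each gene was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, group as the only term and all 8 arrays. Tests were two-sided, with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. The level of Klf7 was also tested with an exact permutation of its 8 values. Of 33 gene lists written before the data were examined, sex-linked genes were described only, and 32 with at least 3 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 32. Members were also counted past 0.05 adjusted over the list alone. Of 806 list members written, 726 were measured, 6 of them under another name. Xist lay between 3.47 and 4.18 and the Y-linked genes Eif2s3y, Kdm5d and Uty between 6.47 and 8.41 on the 8 arrays, with no adjusted p under 0.713.

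The rule for named genes took Klf7 first, then the 12 genes with the highest and the 12 with the lowest log2 fold change among those with an adjusted p under 0.05. Where fewer passed, it took up to 6 genes per direction with the smallest unadjusted p, given as not past the test. It also took up to 4 members per described list by smallest p, and always Kit, Ly6a, Cdkn1a, Cdkn1b and Cdkn1c. Other genes are said to have been named after their values were seen.

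The scripts were tested on simulated data made from the real genes' means and residual spread. For the comparison of KLF7 with control in limma, over 19938 genes, 57% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold were recovered, 0 in the wrong direction, with 8 unchanged genes called. The genes of this simulation were drawn independently of each other. In camera on the same 19938 genes, a list of such independent genes raised by 0.5 log2 was called with either correlation. A shift of correlated genes was not simulated, so the power of the estimated correlation for them is not known. With no effect, 0 of 32 lists were called when genes were independent. When the genes of a list were correlated at 0.5, again with no effect, 15 of 32 were called with the preset correlation and 0 with an estimated one.

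Alternatives left out each array in turn, used the replicate number as a block, normalised again by quantiles, cyclic loess or array medians, weighted the arrays, changed the prior, left out dim genes, averaged the probe sets of a gene, tested all probe sets that were not controls, and changed the thresholds and the tests. Settings that left out both arrays numbered 4, made them a batch term, or left out the arrays labelled KLF7 2 and control 2 were chosen after seeing the data. The labels gave no scan date or slide. Figures were drawn with matplotlib 3.10.9.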

Results

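The expression of mouse haematopoietic stem and progenitor cells was measured 72 hours after transduction with a lentivirus that carried KLF7, a Krüppel-like zinc finger transcription factor, or with a control virus. Bone marrow cells of C57Bl/6 mice that carried the receptor c-Kit were transduced, and the lineage-negative, c-Kit-positive, Sca-1-positive fraction, which is enriched for stem cells and early progenitors, was then sorted. The RNA of each sort was amplified and hybridised to 1 array. There were 4 arrays labelled KLF7 and 4 labelled control, and their number limits the precision of every difference given here. The labels do not say whether the arrays came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. Of 35554 probe sets, 21789 carried 1 gene symbol and gave 19938 genes. The median level of an array lay between 46.2 and 54.1 intensity units, and 2 arrays correlated across genes at 0.936 to 0.982.

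The level of Klf7, the transduced gene, checked the labels. Its probe set, 10355141, had a mean log2 intensity of 10.80 ± 0.55 (SD, n = 4) on the arrays labelled KLF7 and 9.04 ± 1.00 (SD, n = 4) on those labelled control. The difference was 1.76 (SE 0.46, 3.39-fold), with an adjusted p of 0.327 in limma with Benjamini-Hochberg adjustment and a p of 0.0571 in an exact two-sided permutation test, in which the 70 splits allow no p below 0.0286. The groups overlapped in 1 pair of arrays, since the array labelled control 2 (10.28) lay above the array labelled KLF7 2 (10.19). The other control arrays lay at 8.53, 9.35 and 7.98, and the other KLF7 arrays at 11.43, 11.05 and 10.52. The groups are therefore named by their labels throughout, and every direction below is that of arrays labelled KLF7 against arrays labelled control. Whether the probe set reads the transcript of the virus, the cells' own gene or both is not given in the sources used here.

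The design asked which genes differ between cells that overexpress KLF7 and control cells. By the smallest unadjusted p, the genes with higher means on the KLF7 arrays were led by Serpinb6a, an intracellular serine protease inhibitor (difference 1.86 log2, SE 0.28, 3.62-fold), and Zdhhc2, a palmitoyltransferase (1.89, SE 0.29, 3.69-fold). Gnb4, a G protein beta subunit (1.23, SE 0.19), Emp2, a tetraspan membrane protein (1.49, SE 0.23), Map4, a microtubule-associated protein (1.16, SE 0.18), and Dpysl2, a cytosolic phosphoprotein of the cytoskeleton (1.43, SE 0.23), followed. In the other direction stood Fbxl19, an F-box protein that binds unmethylated CpG islands (-0.77, SE 0.13, 1.70-fold lower), Fgf11, an intracellular fibroblast growth factor homologue (-0.98, SE 0.18), and Shfl, an antiviral inhibitor of ribosomal frameshifting (-1.13, SE 0.21, 2.19-fold lower). Srpr, the signal recognition particle receptor (-0.90, SE 0.18), Pcbd1, a pterin dehydratase (-0.80, SE 0.16), and Sec24d, a coat protein of vesicles that leave the endoplasmic reticulum (-0.84, SE 0.17), completed the 12. The 4 KLF7 arrays and the 4 control arrays did not overlap for any of these 12 genes. The genes were picked by smallest p on the same arrays, so this separation is no further support.

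None of these differences passed the test over all genes in the main fit, with group as the only term. In limma with Benjamini-Hochberg adjustment, 0 of 19938 genes had an adjusted p under 0.05, and the smallest, 0.201, was shared by 8 genes: the 6 higher genes just named, L1cam and Myadm, of which Myadm was named after its values were seen. The ordinary two-sample test on each gene also gave 0 genes after adjustment. At an unadjusted p under 0.05 there were 1637 genes, 928 higher and 709 lower, where chance would give 997 on average. Of the 35 splits of the 8 arrays into 4 and 4, 8 reached that count, the real one included. Of the 20 splits that part the arrays numbered 4, only the real one did. Among those 1637 genes, 111 were at least 2-fold higher on the KLF7 arrays and 32 at least 2-fold lower. The groups did not overlap for 1040 genes (5.22%), against 2.86% by chance on average, and overlap was not counted for the other splits. The arrays numbered 4 stood apart from the others in both groups. A limma fit with these arrays as a batch term, chosen after the data were seen, called 26 genes with Benjamini-Hochberg adjustment, 23 higher and 3 lower. A fit without both arrays called 0. The replicate number as a block, an alternative set before the data were examined, called 90 genes with the same adjustment, 75 higher and 15 lower. All 26 were among these 90, and the 26 held the 6 higher genes just named and Shfl. Whether the numbers pair the arrays is not given, so the main fit kept no block.

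**Figure D1:**
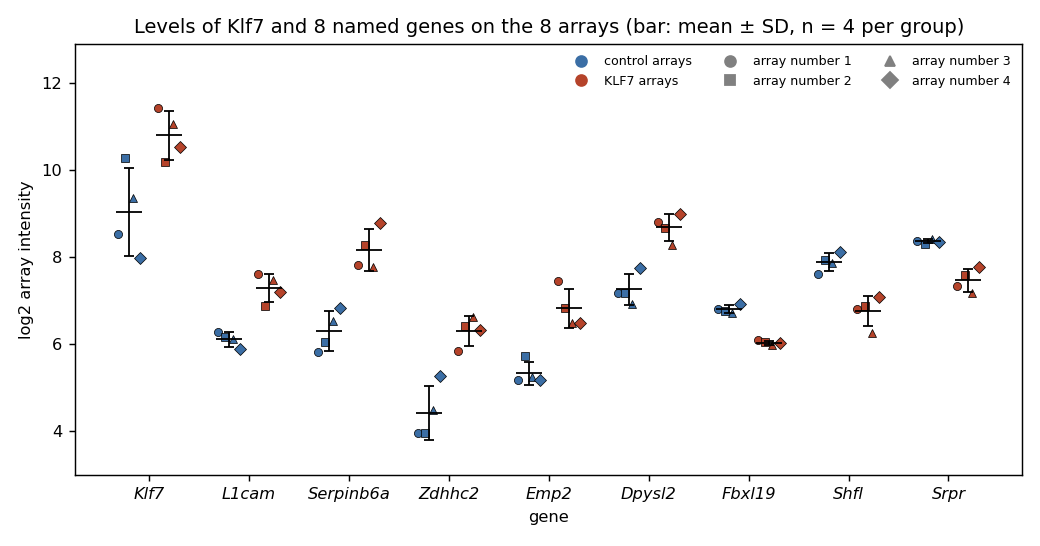
Log2 array intensity of Klf7 and 8 named genes on each array, with control arrays in blue, KLF7 arrays in red, the marker shape giving the array number, and bars showing the mean ± SD of 4 arrays. The groups overlap for Klf7, where the array labelled control 2 (10.28) lies above the array labelled KLF7 2 (10.19). They do not overlap for the other 8 genes, which were named by small p on the same arrays. None of these 8 had an adjusted p under 0.05 in the fit with group as the only term.

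Gene lists fixed before the data were examined were then tested for a shared shift. With camera's preset correlation between genes, 8 of 32 lists had an adjusted p under 0.05. The lists of interferon response genes, of monocyte, macrophage and dendritic cell genes, of NF-kB and inflammatory genes, of apoptosis regulators and of adhesion and homing genes were shifted higher on the KLF7 arrays. The lists of ribosomal protein genes, of unfolded protein response and ATF4 genes and of haematopoietic stem cell genes were shifted lower. With the correlation estimated from the data, which reached 0.877 in 1 list, 0 lists passed (smallest adjusted p = 0.786 with an estimated correlation, 1 list at an unadjusted p under 0.05). How often a true shift of correlated genes would pass there was not simulated. The rotation test fry also gave 0 lists (smallest adjusted p 0.206, 2 lists at an unadjusted p under 0.05). Over all genes 0 list members passed, and 19 list places, held by 17 genes, passed adjusted over the list alone.

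**Figure D2:**
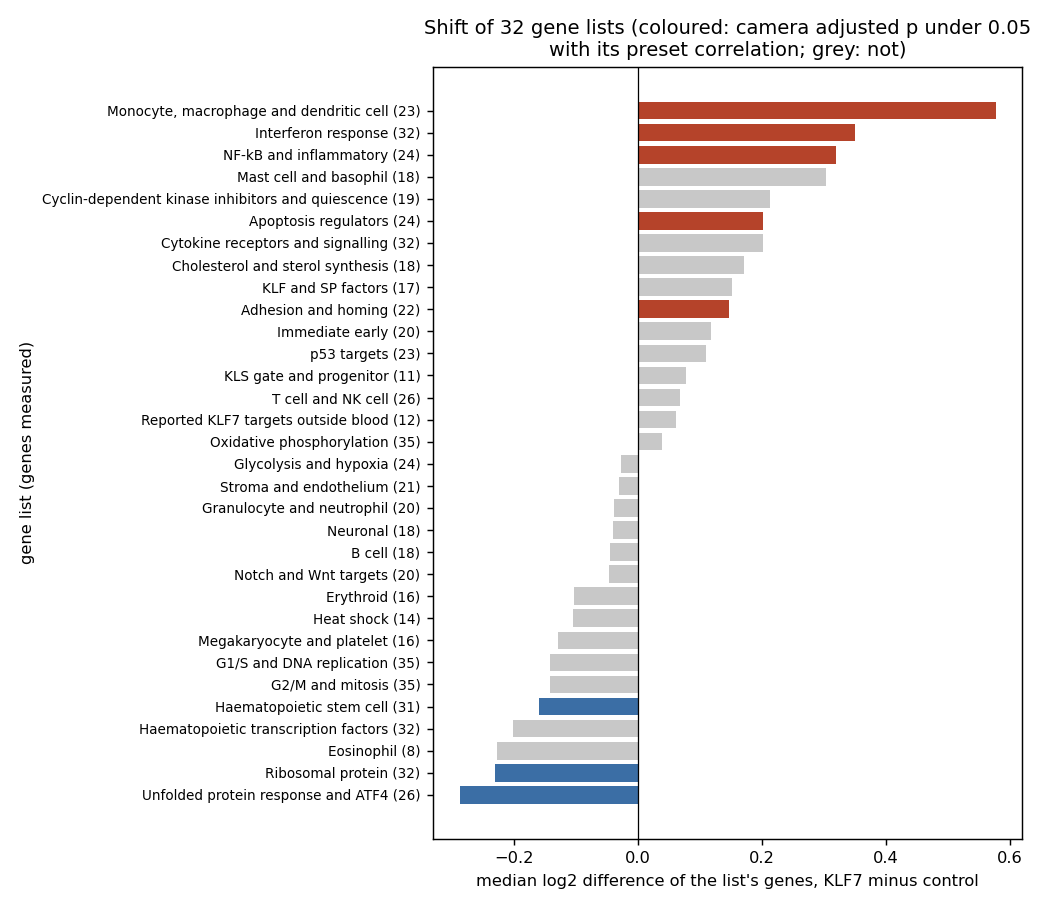
Median log2 difference, KLF7 minus control, of the genes of each of 32 lists, with the number of genes measured in brackets; coloured bars mark the 8 lists with an adjusted p under 0.05 in camera with its preset correlation. The monocyte, macrophage and dendritic cell list has the highest median (0.58) and the unfolded protein response and ATF4 list the lowest (-0.29), and 0 lists passed with an estimated correlation.

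Immune genes made up the 3 lists with the smallest p among the higher ones. Of the 32 measured interferon response genes, which cells transcribe in answer to interferon, 29 had a higher mean on the KLF7 arrays, with a median difference of 0.35 (camera adjusted p = 6.2e-06, and adjusted p = 0.786 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05, all higher. Ifi27l2a differed by 1.83 (SE 0.50, 3.56-fold), Ifit1 by 0.98 (SE 0.33), Zbp1, a sensor of Z-form nucleic acids, by 0.79 (SE 0.27) and Oas3, a 2′-5′ oligoadenylate synthetase, by 0.62 (SE 0.17). The arrays numbered 3 were the lowest for this list in both groups, with mean levels of 6.86 and 6.48 against 7.10 to 7.59 on the other arrays, and the median was 0.23 without the array labelled control 3 and still past the threshold (camera adjusted p = 0.0043).

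Of the 23 monocyte, macrophage and dendritic cell genes, 17 had a higher mean on the KLF7 arrays and the median difference was 0.58 (camera adjusted p = 2.7e-05, and adjusted p = 0.786 with an estimated correlation). Adjusted over the list alone, 5 members passed and were higher, against 0 over all genes. They were Itgax, which encodes the integrin CD11c (1.29, SE 0.38, 2.44-fold), the MHC class II genes H2-Aa (1.41, SE 0.44, 2.65-fold) and H2-Eb1 (1.42, SE 0.45), Adgre1, a macrophage surface receptor gene (0.86, SE 0.27), and the chemokine receptor gene Ccr2 (0.62, SE 0.18). H2-Eb1 was the fifth member and was named after its values were seen. The median was 0.32 without the array labelled control 2, and the list still passed (camera adjusted p = 0.0015). Monocytes, macrophages and dendritic cells are mature cells, which a lineage-negative gate is meant to deplete.

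Of the 24 NF-kB and inflammatory genes, 23 had a higher mean on the KLF7 arrays, with a median of 0.32 (camera adjusted p = 5.1e-05, and adjusted p = 0.786 with an estimated correlation). Adjusted over the list alone, 3 passed, against 0 over all genes: Traf1, an adaptor of tumour necrosis factor receptors (1.53, SE 0.35, 2.89-fold), Cd83, a surface marker of mature dendritic cells (1.22, SE 0.31), and Relb, a subunit of NF-kB (0.91, SE 0.26). The chemokine gene Ccl5 was at 0.93 (SE 0.31), and at 0.59 without the arrays labelled KLF7 2 and control 2. The array labelled KLF7 1 had the highest mean for this list, 8.39 against 7.02 to 7.61 on the other 7 arrays, and without it the median was 0.17 and the call was lost (camera adjusted p = 0.0615), while without KLF7 4 the median was 0.53.

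Apoptosis regulators and adhesion genes were shifted higher by less. Of 24 apoptosis regulators, 21 had a higher mean, with a median of 0.20 (camera adjusted p = 0.0067, and adjusted p = 0.786 with an estimated correlation), and no member had an unadjusted p under 0.05. The anti-apoptotic genes Mcl1 (0.46, SE 0.22), Bcl2l1 (0.33, SE 0.16) and Birc3 (0.31, SE 0.18) and the pro-apoptotic gene Bmf (0.33, SE 0.16) had the smallest p. Without the array labelled KLF7 1, Mcl1 was at 0.27 and Birc3 at 0.16. Without the array labelled KLF7 1 the list's median was 0.13 and the call was lost (camera adjusted p = 0.0823). Of 22 adhesion and homing genes, 14 had a higher mean, with a median of 0.15 (camera adjusted p = 0.0290, and adjusted p = 0.786 with an estimated correlation). The estimated correlation of its genes was 0.0067, and it was the 1 list at an unadjusted p under 0.05 in that test (0.0325). It also had the smallest p of the 32 lists in fry (0.0065, adjusted p 0.206). Adjusted over the list alone, 4 passed, all higher, against 0 over all genes: the chemokine receptor genes Ccr1 (1.14, SE 0.27, 2.20-fold) and Ccr2, and the integrin genes Itgb2 (0.71, SE 0.21) and Itgb1 (0.60, SE 0.18). This list's call was also lost without the arrays labelled KLF7 1 (camera adjusted p = 0.0575), KLF7 3 (0.0649), KLF7 4 (0.0962) or control 2 (0.0706). Leaving out both arrays numbered 4 lost it too (0.0680). In these settings the median lay between 0.12 (without KLF7 1) and 0.15 (without control 2). The median was 0.23 without KLF7 2 and 0.25 with the dimmer 50% of genes left out. The call was lost as well with quantile normalization applied again (median 0.14, 0.0939), with array weights (median 0.08, adjusted p = 0.0806) and in camera on ranks (0.0721).

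Ribosomal protein genes had lower means on the KLF7 arrays for all 32 members measured, with a median of -0.23 (camera adjusted p = 0.00021, and adjusted p = 0.912 with an estimated correlation). None had an unadjusted p under 0.05, and the smallest p belonged to Rps21 (-0.39, SE 0.22), Rpl4 (-0.31, SE 0.19), Rps6 (-0.24, SE 0.15) and Rplp0 (-0.41, SE 0.27). Without KLF7 1, Rps21 was at -0.23 and Rplp0 at -0.25, and Rplp0 was at -0.26 without KLF7 3 and -0.27 without control 4. With array weights these 2 were at -0.25 and -0.27, and without KLF7 2 and control 2 Rpl4 was at -0.47 and Rplp0 at -0.61. The array labelled KLF7 1 had the lowest mean for this list, 10.80, and without it the median was -0.06 and the call was lost (camera adjusted p = 0.345). It was also lost without the array labelled control 4 (median -0.14, adjusted p = 0.0581) and with array weights (median -0.11, adjusted p = 0.0806), while without the arrays labelled KLF7 2 and control 2 the median was -0.35.

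Of 26 genes of the unfolded protein response and of ATF4, the transcription factor of the amino acid response, 22 had a lower mean and the median was -0.29 (camera adjusted p = 0.0011, and adjusted p = 0.786 with an estimated correlation). The stress gene Ddit4 was at -0.45 (SE 0.18), the lipoprotein receptor gene Vldlr at -0.61 (SE 0.28), and Psat1 and Phgdh, enzymes of serine synthesis, at -0.92 (SE 0.43) and -0.90 (SE 0.43). Without the array labelled KLF7 1, Vldlr was at -0.32, Psat1 at -0.42 and Phgdh at -0.52, and Phgdh was at -0.51 with array weights. Without the array labelled KLF7 1, which was again the lowest (7.95), the median was -0.07 and the call was lost (camera adjusted p = 0.169), as it was with array weights (median -0.14, adjusted p = 0.0806), while the median was -0.44 without KLF7 2 and -0.45 without KLF7 2 and control 2.

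Of 31 haematopoietic stem cell genes, 21 had a lower mean, with a median of -0.16 (camera adjusted p = 0.0113, and adjusted p = 0.786 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05, all lower. They were Hlf, a transcription factor gene of stem cells (-0.90, SE 0.23, 1.87-fold lower), Adgrg1, which encodes the adhesion receptor GPR56 (-1.44, SE 0.47, 2.72-fold lower), Trpc6 (-0.71, SE 0.31) and Gstm5 (-1.05, SE 0.47), with Adgrg1 at -0.95 without KLF7 1 and Gstm5 at -0.63 without control 4. The call was lost without the arrays labelled KLF7 1 (camera adjusted p = 0.0823), KLF7 3 (0.0618) or control 4 (0.327). It was also lost without both arrays numbered 4 (0.0680) and with array weights (0.0806). In these settings the median lay between -0.12 (without control 4) and -0.16 (without KLF7 3), while without KLF7 4 it was -0.25. With the dimmer 50% of genes left out the median was -0.38 and the list passed (camera adjusted p = 0.0037).

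**Figure D3:**
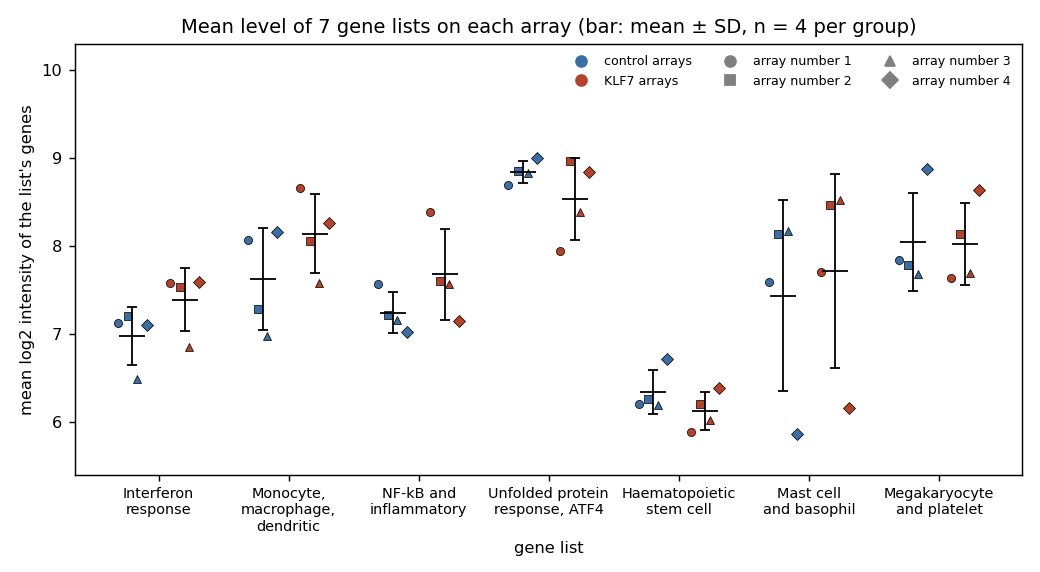
Mean log2 intensity of the genes of 7 lists on each array, with control arrays in blue, KLF7 arrays in red, the marker shape giving the array number, and bars showing the mean ± SD of 4 arrays. The arrays numbered 4 are the lowest of each group for mast cell and basophil genes (6.16 and 5.86) and the highest for megakaryocyte and platelet genes (8.63 and 8.88), and the arrays numbered 3 are the lowest of each group for interferon response genes (6.86 and 6.48).

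KLF7 has been studied most outside blood, and 12 genes reported there as its targets were measured. The list was not divided by the reported direction of each target, so members moving opposite ways would cancel in the median and test. The median difference of the 12 was 0.06 (camera adjusted p = 0.427), with 8 higher and 4 lower, which does not show whether the targets responded. It was -0.0012 without the array labelled KLF7 1 and -0.0073 without control 3, against 0.13 without KLF7 3 and 0.03 without KLF7 2 and control 2. L1cam, which encodes a neural cell adhesion molecule, was 2.26-fold higher on the KLF7 arrays (difference 1.18, SE 0.19) at 7.29 ± 0.32 against 6.12 ± 0.17 (SD, n = 4 each), and was the 1 member past the threshold adjusted over the list alone (adjusted p 0.00087 there and 0.201 over all genes, limma). With the arrays numbered 4 as a batch term, chosen after the data were seen, L1cam passed over all genes in limma (adjusted p 0.0428). Its difference lay between 1.07 and 1.31 when each array was left out in turn. L1cam is also on the neuronal list, where it was again the 1 member past the threshold adjusted over the list alone. The others stayed short of the test, with Cebpa at -0.59 (SE 0.29), Gap43, a growth cone protein gene, at 0.19 (SE 0.13) and Fabp4, a fatty acid binding protein gene of fat cells, at 0.28 (SE 0.24). Without KLF7 1, Cebpa was at -0.36 and Gap43 at 0.10, and without KLF7 2 and control 2 they were at -0.92 and 0.30. Fabp4 lay between 0.14 (without control 3) and 0.54 (without both arrays numbered 4).

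Among 17 other KLF and SP factors, 12 had a higher mean, with a median of 0.15 (camera adjusted p = 0.422). It was 0.23 without the array labelled control 1 and 0.08 without both arrays numbered 4. Adjusted over the list alone 4 passed, against 0 over all genes: Klf10 (0.68, SE 0.17) and Klf8 (0.67, SE 0.22) were higher, and Klf9 (-0.65, SE 0.18) and Klf2 (-0.59, SE 0.18) were lower. The median of the 19 cyclin-dependent kinase inhibitor and quiescence genes was 0.21 (camera adjusted p = 0.0702). It was 0.06 without the array labelled KLF7 1, 0.12 with array weights and 0.11 without KLF7 2 and control 2. In that list Rb1, the retinoblastoma gene, passed adjusted over the list alone (0.77, SE 0.18, 1.70-fold), while Foxo1 (0.44, SE 0.16), Cdkn2b (0.35, SE 0.14), Cdkn1b (0.15, SE 0.27) and Cdkn1c (0.08, SE 0.14) did not. Without 1 array Cdkn1b lay between -0.04 (KLF7 1) and 0.33 (control 3) and Cdkn1c between 0.02 (KLF7 1) and 0.18 (KLF7 4). Without 1 of the arrays labelled KLF7 4, control 1 or control 3 this list passed in camera (adjusted p = 0.0210, 0.0429 and 0.0232), and each of these calls was lost with an estimated correlation (adjusted p = 0.558, 0.749 and 0.950).

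The genes of the sort gate and of progenitors showed no shift as a set (11 measured, median 0.08, camera adjusted p = 0.837). The median lay between -0.02 without KLF7 4 and 0.26 without control 4. Kit, the receptor used in the sort, differed by 0.31 (SE 0.56), with 9.68 ± 1.24 on the KLF7 arrays and 9.36 ± 0.69 on the control arrays (SD, n = 4 each), and by -0.03 without control 4 and 0.92 without KLF7 4. Either of these fits leaves an array numbered 4 in 1 group alone, and those arrays differed from the others by -1.90 for Kit. Satb1, a chromatin organiser gene of lymphoid progenitors, was at -0.44 (SE 0.16), Il7r at 0.93 (SE 0.42), Cd48 at 0.44 (SE 0.29) and Cd27 at -0.59 (SE 0.49). Il7r was at 0.46 without KLF7 1, and Cd48 at 0.66 without KLF7 3 and 0.25 without KLF7 4. Cd27 was at -0.29 without KLF7 1, -1.05 without KLF7 4 and -0.22 without control 4. The median of the 18 mast cell and basophil genes was 0.30 (camera adjusted p = 0.121), with Rgs13 at 0.30 (SE 0.12), Mitf at 0.62 (SE 0.29), Mcpt2 at 0.41 (SE 0.22) and Mcpt4 at 0.54 (SE 0.44). Rgs13 (mean 2.86 on the KLF7 arrays against 2.56) and Mcpt2 (3.58 against 3.17) were among the dimmest genes on the arrays. Mcpt4 was at 0.08 without KLF7 2, 0.87 without KLF7 4, 0.96 with array weights and 0.20 without KLF7 2 and control 2. Mcpt2 was at 0.22 without KLF7 3 and Mitf at 0.37 as the mean of its probe sets. The list median was 0.83 without the array labelled KLF7 4 (camera adjusted p = 0.00013), 0.43 without control 2 (0.0171), 0.49 without control 3 (0.0043) and -0.14 without control 4 (0.563). It was 0.07 without KLF7 2 and 0.06 without KLF7 3, and with the arrays numbered 4 as a batch term the list passed at the same median (camera adjusted p = 0.0151). With an estimated correlation this list stayed short of the threshold over all 8 arrays (adjusted p = 0.953), and the calls without KLF7 4, control 2 or control 3 and with the batch term were lost (adjusted p = 0.658, 0.869, 0.950 and 0.801).

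In the fit of all 8 arrays, lists of other cell types and of the cell cycle stayed short of the threshold. The median was -0.14 for 35 genes of G1/S and DNA replication (camera adjusted p = 0.0522), -0.14 for 35 genes of G2/M and mitosis (0.201) and -0.20 for 32 haematopoietic transcription factors (0.138). It was 0.17 for cholesterol and sterol synthesis (0.0580), 0.20 for cytokine receptors and signalling (0.146), 0.07 for T cell and NK cell genes (0.204), -0.10 for erythroid genes (0.432), -0.13 for megakaryocyte and platelet genes (0.904) and -0.04 for granulocyte and neutrophil genes (0.607). Medians of -0.05 for B cell genes (0.812), -0.23 for eosinophil genes (0.607), -0.03 for stroma and endothelium (0.904) and 0.11 for p53 targets (0.904) were also short of it. The remaining lists were heat shock (-0.10, 0.446), immediate early (0.12, 0.446), glycolysis and hypoxia (-0.03, 0.592) and oxidative phosphorylation (0.04, 0.883). In the neuronal list (median -0.04, mean 0.03, adjusted p 0.904) the test ran higher, and in the Notch and Wnt target list (median -0.05, mean 0.05, adjusted p 0.957) it ran lower, so that median, mean and test differed in sign. Leaving out 1 array moved each of these medians by over 1.5 times and turned several. Cholesterol synthesis lay between 0.03 without KLF7 4 and 0.31 without control 4. In the same order, megakaryocyte and platelet genes lay between -0.35 and 0.16, oxidative phosphorylation between -0.18 and 0.27, heat shock between -0.23 and 0.05 and G1/S between -0.29 and 0.01. Eosinophil genes lay between -0.56 (without control 4) and 0.14 (without control 1). Granulocyte genes lay between -0.53 (without control 4) and 0.15 (without control 3) and immediate early genes between -0.15 (without control 4) and 0.47 (without KLF7 4). Without KLF7 1 the median was -0.04 for p53 targets, -0.05 for G2/M, -0.03 for erythroid genes, 0.05 for glycolysis and hypoxia and -0.0039 for T cell and NK cell genes. It was -0.12 for haematopoietic transcription factors without control 1 and 0.10 for cytokine receptors without control 4. Without KLF7 4 it was 0.00082 for B cell genes, 0.03 for stroma and endothelium, 0.06 for Notch and Wnt targets and -0.0042 for neuronal genes.

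Some of these calls turned on the setting. Leaving out only KLF7 4 or only control 4 leaves an array numbered 4 in 1 group alone. Those fits therefore mix the array number with the group, here and in the medians above. Of 19 alternative settings in camera with its preset correlation, the G1/S and DNA replication list passed in 11, each time lower. Among them were the fits without 1 of the arrays labelled KLF7 2 (adjusted p = 0.0411), KLF7 4 (0.00013), control 1 (0.0112), control 2 (0.0093) or control 3 (0.0232), without both arrays numbered 4 (0.0217) and with these as a batch term (0.0284). Cholesterol and sterol synthesis passed in 9, each time higher, among them without KLF7 2 (0.0142), KLF7 3 (0.0449), control 3 (0.0467) or control 4 (0.00033), without both arrays numbered 4 (0.0201) and with these as a batch term (0.0354). Both lists also passed with quantile normalization (0.0186 and 0.0339), cyclic loess (0.0472 and 0.0322) and no intensity trend (0.0428 and 0.0453). With an estimated correlation all of these calls were lost, at an adjusted p of 0.620 to 0.962 for G1/S and of 0.678 to 0.950 for cholesterol synthesis. Cytokine receptors and signalling passed without KLF7 4 (0.0149), without both arrays numbered 4 (0.0330) and with the batch term (0.0379), and G2/M and mitosis without KLF7 4 (0.0095), without control 1 (0.0331) and without both arrays numbered 4 (0.0129). Both were lost with an estimated correlation (adjusted p of 0.558 to 0.676 and of 0.658 to 0.854). Granulocyte and neutrophil genes passed, lower, without KLF7 3 (0.0449) or control 4 (0.0204), immediate early genes without KLF7 4 (0.0351), and T cell and NK cell genes without both arrays numbered 4 (0.0201), and with an estimated correlation these had an adjusted p of 0.803 and 0.841, 0.658 and 0.578. Oxidative phosphorylation genes passed in opposite directions, higher without KLF7 1 (0.0263) or control 4 (0.0195) and lower without KLF7 4 (0.0241) or without the arrays labelled KLF7 2 and control 2 (0.0223). With an estimated correlation these calls were lost as well (adjusted p of 0.846 to 0.919).

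The array number went with large differences inside both groups. On the arrays numbered 4, the median mast cell and basophil gene was -2.36 log2 from the other arrays of its group, with 17 of 18 genes lower, and the median granulocyte and neutrophil gene was at -1.21. Cpa3, the mast cell carboxypeptidase, lay at 8.0 and 7.48 on the arrays numbered 4 and at 11.11 to 12.56 on the others, a mean difference of -4.32. Kit lay at 7.85 and 8.33 against 9.57 to 10.52, and Mpo, the myeloperoxidase of granulocyte precursors, at 8.72 and 9.73 against 9.52 to 12.41. Megakaryocyte and platelet genes (median 1.30) and oxidative phosphorylation genes (0.81, higher for all 35) ran the other way. For the lists called above, the median without these 2 arrays and the median difference between the 2 of them were 0.31 and 0.44 for interferon response, 0.68 and 0.28 for monocyte, macrophage and dendritic cell, 0.40 and 0.07 for NF-kB and inflammatory, and 0.22 and 0.11 for apoptosis regulators. They were 0.14 and 0.23 for adhesion and homing, -0.24 and -0.17 for ribosomal protein, -0.33 and -0.14 for unfolded protein response and ATF4, and -0.12 and -0.35 for haematopoietic stem cell. With the arrays numbered 4 as a batch term, camera with its preset correlation called 12 lists, the 8 called without the term among them, and 0 with an estimated correlation.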

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

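The tests of the 2 explanations for the Klf7 levels, of both monocyte and macrophage gene sets and of the arrays numbered 4 for the MHC class II genes, and of normalization for the arrays numbered 4 were chosen after the result was seen. The tests of other dendritic-line genes and of other mast cell and basophil genes were written before those genes' values were looked at. Their gene lists were still drawn up after the fit, to address patterns seen on the same 8 arrays. Among 158 groups of 4 arrays, for the named genes and the described lists, 10 held an array far from the other 3 by Dixon's test, where chance gives about 1 in 20, or 7.9.

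Arrays that shared a number stood apart together in some of these. For Klf2, the array labelled KLF7 4 (6.41) lay below the other KLF7 arrays (6.77 to 6.80, ratio 0.934) and the array labelled control 4 (6.89) below the other control arrays (7.41 to 7.42, ratio 0.984). For the interferon response list, the array labelled KLF7 3 (6.86) lay below 7.53 to 7.59 (ratio 0.915) and the array labelled control 3 (6.48) below 7.10 to 7.20 (ratio 0.861). The array labelled KLF7 1 stood above the others for Birc3 (7.63 against at most 7.01, ratio 0.982) and for the apoptosis regulator list (7.60 against 7.28 to 7.33, ratio 0.856). Among control arrays, number 4 stood above for the haematopoietic stem cell list (6.71 against 6.19 to 6.26, ratio 0.868), number 2 for Emp2 (5.73 against 5.18 to 5.24, ratio 0.896) and number 1 for Oas3 (6.90 against 6.46 to 6.52, ratio 0.847). Number 1 stood below for Rps6 (11.95 against 12.08 to 12.11, ratio 0.845).

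The array labelled control 2 had more Klf7 signal than the array labelled KLF7 2. On the 100 genes with the smallest p in the other 6 arrays, Klf7 left out, the array labelled KLF7 2 lay 0.471 nearer the KLF7 mean than control 2 did, beyond the spread of this difference over the 4 pairs (SD 0.162), which argues against a swap of the 2 arrays. The array labelled control 2 lay at 0.183, where 0 is the control mean and 1 the KLF7 mean of the other arrays, which argues against its being a KLF7 array (SD of the 4 control positions 0.229). What raised its Klf7 signal stays open, and no biological explanation was tested.

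The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a mean 1.22 log2 higher on the KLF7 arrays (SE 0.52, exact permutation p 0.0571). Without both arrays numbered 4 the difference was 1.48, so these arrays do not account for it. Over all 8 arrays it exceeded that of 7 macrophage genes, C1qa, C1qb, C1qc, Mrc1, Cd68, Cd14 and Csf1r (mean -0.0017, SE 0.47), by 1.22. The exact permutation p was 0.0286, the smallest that 70 splits give. The MHC class II genes and the 7 were set against each other after the result was seen, and this p was not adjusted. It therefore decides nothing about cells marked by those 7. The MHC class II difference exceeded that of all 16 monocyte and macrophage genes of the fixed list, Adgre1, Mpeg1, Cybb and Fcgr1 among them (mean 0.36, SE 0.36), by 0.855 (SE 0.35, exact permutation p 0.0571). This decides neither way, so more cells of the monocyte and macrophage line stay open. Without 1 array the mean of the 7 ran from -0.23 (control 3) to 0.31 (control 1). That of the 16 ran from 0.19 (control 2) to 0.56 (control 1). The excess ran from 0.94 to 1.48 over the 7 and from 0.64 to 1.08 over the 16. The mean of 38 other dendritic-line genes was 0.507 higher (SE 0.17, exact permutation p 0.0286, 0.0714 after adjustment over 5 tests), 31 of 38 higher, so more dendritic-line cells past the lineage gate, or more dendritic-line expression within the sorted cells, may contribute, and the 2 were not separated here. Of these 38 genes, 2 are on another list and 26 lay above the median gene in control arrays, and the most abundant were Tmem123 (9.57 against 8.94), Wdfy4 (9.34 against 8.83), Sirpa (9.21 against 8.95) and Samsn1 (8.78 against 8.61).

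The arrays numbered 4 stood apart in both groups. Normalising again by quantiles left the mast cell and basophil list at -2.34 or lower in both groups. Array medians already lay close, between 46.2 and 54.1 intensity units, so this step could hardly have moved 1 list that far. It shows only that no difference of scale between arrays remained to account for the drop. The deposited values were already normalised by RMA, and that earlier step was not tested by this. Fewer mast cells and basophils in those sorts is a candidate cause: the median of 15 other genes of these cells was -0.0824 on the KLF7 array (SE 0.252) and -0.22 on the control array (SE 0.275), with 8 lower and 5 higher on both arrays. The bound set beforehand against this cause was met on the KLF7 array, but by less than the error, a requirement applied after the value was seen, so the test decides neither way, and Mrgprb2, Mrgprb1 and Enpp3 were among the dimmest genes on the arrays. A difference in the sort, in the animals or in the RNA of those preparations stays open and was not tested.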

How the results depend on the processing

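The settings with the arrays numbered 4 or the pair numbered 2 were chosen after seeing the data. The count of 0 changed genes held in all settings but those named next (1637 genes at an unadjusted p under 0.05; smallest adjusted p 0.201). Leaving out 1 array gave 0 to 1 genes: Phf11a without KLF7 3 (1.36, adjusted p 0.0247), named after its values were seen, and Zdhhc2 without control 4 (2.17, adjusted p 0.0288, 0.0167 to 0.800 over its settings). A fit with the arrays numbered 4 as a batch term gave 26 genes, 2 list places over all genes and 40 adjusted over the list alone.

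With the replicate block, limma with Benjamini-Hochberg adjustment called 90 genes (75 higher, 15 lower), L1cam (adjusted p 0.0309) among them, 11 list places over all genes and 82 adjusted over the list alone, and camera 12 lists, mast cell and basophil genes (adjusted p 0.0016), G1/S, cholesterol synthesis and cytokine receptors newly among them; with an estimated correlation it called 0 (smallest adjusted p of the 12 0.348, mast cell and basophil 0.390). The pairing was checked by the correlation of same-numbered arrays' deviations: 0.350, -0.126, 0.362 and 0.699 for numbers 1 to 4. Number 2 showed none, but numbers 1, 3 and 4 were positive and 6 of 8 arrays correlated best with their own number. A pairing by number therefore stays open. The labels do not state one, and the main fit kept no block, as the design had set. All 26 genes of the batch term were among these 90.

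The 8 called lists became 4 with array weights, 0 with an estimated correlation and 0 with fry, and 3 (without KLF7 1) to 14 (without KLF7 4) when 1 array was left out. Over all settings the lowest adjusted p of the called lists was 1.9e-12 (interferon response) and the highest 0.912 (ribosomal protein). The robust prior was not run for lists, since camera does not use it. The 19 places adjusted over the list alone became 12 with quantile normalization again, 3 without the arrays labelled KLF7 2 and control 2, and 2 (without control 3) to 20 (without control 4) without 1 array; without KLF7 1, KLF7 2, KLF7 4, control 1 and control 2 they were 9, 10, 5, 4 and 5. The Klf7 difference stayed between 1.40 and 2.38 and short of the threshold in each setting. Directions turned without 1 array: Cdkn1b ran from -0.039 to 0.33, Kit from -0.028 to 0.92, the gate and progenitor list median from -0.025 to 0.26 and the mast cell and basophil list median from -0.14 to 0.83. The gate list was at -0.012 without control 3, and the reported-target list median ran from -0.0073 to 0.13. Fewer arrays and, for array weights, less weight on the arrays labelled KLF7 4 (0.504), control 4 (0.586) and KLF7 1 (0.669) are part of these settings. A fit without only KLF7 4 or only control 4 leaves the other array numbered 4 in 1 group alone. Those arrays differed from the others by -1.90 for Kit and -2.36 for the mast cell and basophil median. The swings of Kit and of this list in these fits ran the way this imbalance would move them. The cause was not tested otherwise. Of the single genes, 1328 values kept direction and side of the threshold, 21 newly passed and 2 reversed. The number of arrays limits all of this.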

Other observations

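The tests of the S100, annexin, small nucleolar RNA and ribosome biogenesis genes were written before those genes' values were seen, but after other members of the families had drawn attention; genes named in this part were chosen after their values were seen. With the arrays numbered 4 as a batch term, limma with Benjamini-Hochberg adjustment called the S100 genes S100a4 (2.17, SE 0.24, 4.49-fold higher), S100a10 (1.76, SE 0.19) and S100a6 (1.76, SE 0.23), the annexin gene Anxa5 (1.11, SE 0.16), the LIM domain gene Crip1 (1.5, SE 0.18), the calpain gene Capn2 (1.02, SE 0.16) and Myadm, a myeloid differentiation marker (1.52, SE 0.22). The largest difference among the 26 calls was that of Plet1, a surface protein of epithelial and some dendritic cells (2.46, SE 0.37, 5.49-fold higher), and Slc6a4, the serotonin transporter gene, was at 1.37 (SE 0.15). Il12a (-1.20, SE 0.18), Snora44 (-1.19, SE 0.17) and Shfl were the 3 lower ones. In the main fit, with group as the only term, each of these had an adjusted p of 0.201 or more.

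The following genes passed no adjustment. Thy1 (1.83, SE 0.45) and Klrd1 (2.01, SE 0.56), surface proteins of T and NK cells, had higher means on the KLF7 arrays, as did the transcription factor genes Irf4 (1.31, SE 0.44) and Id2 (0.87, SE 0.28). Csf3r, the receptor gene of granulocyte colony-stimulating factor (-1.13, SE 0.30), the progenitor regulators Myb (-0.91, SE 0.24) and Myc (-0.63, SE 0.17) and the replication licensing gene Cdc6 (-0.71, SE 0.18) had lower means. The smallest adjusted p among these 8 was 0.327 in limma.

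It was asked whether family members not yet looked at move with the seen ones, with exact permutation tests over 70 splits, 5 of them counting the dendritic-line test. The mean of 8 other S100 genes was 0.238 higher on the KLF7 arrays (SE 0.09, exact permutation p 0.0286, the smallest possible, 0.0714 adjusted), with 6 of 8 higher and the mean above the control mean on 4 of 4 arrays, so a wider shift of the family may be present, although 2 of the 8 lay above the median gene in control arrays. The mean of 8 other annexin genes was 0.135 higher (SE 0.07, exact permutation p 0.0857, 0.107 adjusted), with 4 higher and 4 lower and a median of 0.03, and 0.07 without the array labelled control 4. Anxa11 (0.52, SE 0.20) and Anxa2 (0.45, SE 0.19) had the smallest p. For 46 other small nucleolar RNA genes it was -0.368 (SE 0.20, exact permutation p 0.0571, 0.0952 adjusted), with 38 lower. For 44 ribosome biogenesis genes it was -0.388 (SE 0.24, exact permutation p 0.20, 0.20 adjusted), with 42 lower and the mean at -0.25 without KLF7 3, among them Polr1a (-0.64, SE 0.20), Nop56 (-0.70, SE 0.23) and Ncl (-0.59, SE 0.20). The last 3 tests leave their hypotheses undecided.

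The 35 splits of the 8 arrays into 4 and 4 were fitted in the same way. The real split gave 0 genes past adjusted p 0.05, which all 35 reach whatever their values, so this count tests nothing (highest other 8). It gave 1637 genes at an unadjusted p under 0.05, a count reached by 8 of 35 (highest other 3206, for the arrays labelled KLF7 1, KLF7 3, control 1 and control 2 against the rest). It gave 8 lists, a count reached by 23 of 35 (highest other 17), and 19 list members adjusted over the list alone, a count reached by 5 of 35 (highest other 76). Over all 35 splits, chance is excluded for none of the last 3 counts, but these splits do not keep the arrays numbered 4 apart as the real one does. The 7 other splits with as many genes at an unadjusted p under 0.05 all kept both arrays numbered 4 on one side, as 15 of the 35 splits do, and the highest, 3206 genes, came with the highest count of list members, 76 against 19, which points to a structure of the arrays other than the labels. Among the 20 splits that part these arrays, looked at after the counts were seen, the highest other count was 858 genes at an unadjusted p under 0.05, 11 lists and 11 list members, against 1637, 8 and 19. These 20 splits are too few for a share under 0.05. With these arrays as a batch term the real comparison gave 26 genes, but no other split was fitted with that term, so this count has no reference among the splits.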
